A study of Mus musculus with 6 samples.

How the data were processed

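Total RNA from the granule cell layer of the mouse cerebellum was profiled on 6 Affymetrix arrays, 3 of the PTEN cKO group and 3 of the Ctrl group. Per the labels' protocols, the layer was isolated by laser capture microdissection, RNA was extracted with Trizol and cleaned on RNeasy columns, and biotin-labelled cRNA was made from amplified cRNA. The labels give all 6 samples as from male mice aged 3 months. Groups and replicate numbers were taken from the sample titles.

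The deposited values are 1 intensity per probe set and array, which the submitters' processing notes link to RMA and Partek, with versions not given in the sources used here. RMA corrects the background, equalises the distributions of the arrays and summarises the probes of a set. The deposited intensities ran from 3.907 to 17527.7, which is a linear scale, so log2 was taken before any test. The design fixed in advance had assumed log2 values or this step. Array medians then lay between 5.00 and 5.03 on the log2 scale and lower quartiles between 3.42 and 3.48. The values were not normalized again, and 0 value columns were left unmapped. Equalised distributions remove any overall shift in RNA amount, so each change is relative to the other genes of an array. Amplification of small RNA amounts favours the 3' ends of transcripts, and dim probe sets are compressed towards the background, so folds from a dim group are uncertain in size. No detection calls were used here.

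The arrays hold 22690 probe sets. Of these, 64 are controls and were left out of the tests, 20380 (89.8%) name 1 gene symbol in the platform annotation, 691 name several and 1555 name none there. Of the probe sets with 1 symbol, 20351 matched a mouse gene by Entrez identifier in the RefSeq table of assembly GRCm38.p6, 29 did not, and 0 symbols needed an update. Probe sets with several symbols or none entered no gene test. Each gene was represented by its probe set with the highest mean over all arrays, which gave 12393 genes, and the values of a gene's other probe sets are given in the report for the genes of largest change, and for other genes named there where the probe sets differ in sign. Several familiar symbols, Pten among them, have no probe set named for them in this annotation and were not analysed here. No coordinates were used.

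Gene differences were tested with limma (lmFit and eBayes without trend, version 3.58.1, in R 4.3.3) on log2 intensities, PTEN cKO against Ctrl with no covariate, and p-values were adjusted by Benjamini-Hochberg over the 12393 genes with a threshold of 0.05. Errors of log2 fold changes are limma's moderated standard errors, and confidence intervals are at 95%. An exact permutation test of 3 against 3 arrays cannot give a two-sided p under 0.1, so none is given for single genes. Gene lists were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over 33 lists, and again with an estimated correlation and with fry. With an estimated correlation, camera also lowers its degrees of freedom to the residual 4 of the arrays, so a call lost there is not lost to the correlation alone. A run with the estimated correlation of each list and the degrees of freedom of the preset test was added after the data were seen. The lists, with 1313 symbols of which 1081 were measured, were written before the data were examined and cover pathways of PTEN signalling, metabolism, axons and synapses, and markers of the cell types a capture could hold. For each list, the number of changed members is given over all genes tested and adjusted over the list alone. Lists share some genes.

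The rule for named genes, also set before the data were examined, took Pten, the 12 genes with the largest increase and the 12 with the largest decrease among those past the threshold whose groups did not overlap, and the 4 members of each list with the smallest p. Genes outside it are said to be chosen after their values were seen. Tables were prepared with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6.

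The gene and list tests were tested on simulated data, 20 sets of 12393 genes for the comparison of PTEN cKO with Ctrl, each with 200 changed genes. They recovered 39.8% of genes changed by 0.5 on the log2 scale, 99% of those changed by 1 and 100% of those changed by 2 or 3, with 6.44% false among the calls. A list shifted by 0.5 was called in 20 of 20 simulations. Without any change, a mean of 0.2 genes and 0.05 lists was called. The simulated noise was drawn independently for each gene, so these list results do not cover correlation between the genes of a list. Other splits of the real arrays gave up to 7 lists, but each of these splits mixed both groups, so part of the group difference stays in them.

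The alternatives were an intensity trend with and without robust moderation, quantile normalization, centring on array medians, leaving out the genes under the lower quartile or under the median by mean intensity, other ways to summarise a gene's probe sets, array weights, the replicate number as a block, and leaving out each array in turn. Their effects are given in the closing section.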

Results

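Gene expression was measured in the granule cell layer of the adult mouse cerebellum, the layer that holds the small, densely packed, glutamatergic granule neurons. The layer was cut from brain sections by laser capture microdissection, and its RNA was amplified and hybridised to Affymetrix arrays. PTEN is a lipid phosphatase that opposes PI3K signalling. Male mice aged 3 months were compared in 2 groups, conditional mutants that lack PTEN in granule cells (PTEN cKO, 3 arrays) and wild-type controls (Ctrl, 3 arrays). The comparison asks which transcripts of the layer differ when its granule cells lack PTEN. The number of arrays limits the precision. The labels do not say whether replicates came from separate animals, so p-values measure only the spread between these samples, which may be technical. No probe set was named Pten in the annotation used here, so the targeted gene was not analysed here and the labels were not checked against it.

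The arrays separated by genotype. Correlations of log2 intensity over 12393 genes lay between 0.9927 and 0.9952 for pairs of arrays of the same group, and between 0.9807 and 0.9855 for pairs of different groups. The first principal component held 60.4% of the variance and had all 3 PTEN cKO arrays on one side and all 3 Ctrl arrays on the other. On the second component, with 13.2% of the variance, Ctrl replicate 3 stood apart at −20.1, while the other arrays lay between −5.3 and 9.4. In PTEN cKO, 832 genes were higher and 716 were lower at an adjusted p under 0.05, together 1548 genes or 12.5% of those tested, and 3207 had an unadjusted limma p under 0.05. At least 2-fold changes were seen for 191 of the higher and 112 of the lower genes. All values of one group lay above all values of the other for 3721 genes (30.0%), where chance gives 10%. The counts of higher and lower genes were 723 and 729 without Ctrl replicate 3, 508 and 422 without PTEN cKO replicate 2, 552 and 438 without PTEN cKO replicate 3, and 627 and 445 without Ctrl replicate 1.

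The largest increases were in genes for a transcription cofactor, a neuropeptide, a Ras-association domain protein and a neurofilament. Dach2, a dachshund-family transcription cofactor, was 36.2-fold higher in PTEN cKO (adjusted p = 5.79e-07), at a mean log2 intensity of 8.51 ± 0.24 against 3.33 ± 0.18 in Ctrl (SD, n = 3 per group). Nts, which encodes the precursor of neurotensin, was 32.8-fold higher, at 8.85 ± 0.44 against 3.82 ± 0.14. The Ctrl means of Dach2 and Nts lay below the medians of the control probe sets of the arrays (4.35 to 4.45), so the size and rank of their folds rest on dim Ctrl signals and are uncertain. Rassf3 rose 20.5-fold on its brightest probe set, and its 3 probe sets ranged from 0.34 to 4.36 on the log2 scale. Nefh, the heavy neurofilament chain, was 13.8-fold higher (95% confidence interval 8.65 to 22.0), at 9.85 ± 0.66 against 6.07 ± 0.35. Ccnd1, which encodes cyclin D1, rose 9.56-fold (7.13 to 12.8), with all 3 probe sets between 2.41 and 3.26. Limk1, the kinase that phosphorylates cofilin, rose 8.05-fold on its brighter probe set, while the other gave −0.05. Elavl2, a neuronal RNA-binding protein, rose 7.74-fold on its brightest probe set from an already bright signal of 8.96 ± 0.26, and its 5 probe sets ranged from 0.18 to 3.22. The other genes with large increases were D430019H16Rik (13.6-fold), Mpzl2 (7.78-fold, 3 probe sets from 0.48 to 2.96), the HIF prolyl hydroxylase Egln3 (7.39-fold, 2 probe sets at 1.95 and 2.89), Cdr2 (7.24-fold) and the IGF-binding protein Igfbp4 (7.17-fold), whose 6 probe sets ranged from −0.13 to 2.84. Egln3 too had a Ctrl mean (4.11 ± 0.29) below those medians, so the size and rank of its fold are uncertain.

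The largest decreases included an ion pump regulator, Wnt pathway genes, calcium sensors and signalling genes. Fxyd6, a regulator of the sodium pump, was 8.80-fold lower in PTEN cKO (adjusted p = 7.63e-05). Its PTEN cKO mean, 3.86 ± 0.46, lay below the medians of the control probe sets of the arrays (4.35 to 4.45), so the size and rank of its fold are uncertain. The Wnt receptor gene Fzd7 was 6.71-fold lower on its brighter probe set, while the other gave 0.09, and Dact1, whose product binds dishevelled, was 5.59-fold lower. Car9, a carbonic anhydrase gene, fell 6.73-fold. Among genes of calcium sensing, Hpcal1 fell 5.48-fold, Syt9 4.71-fold and Doc2b 4.09-fold on its brighter probe set, while the other gave −0.31. Bcl2l11, which encodes the pro-apoptotic protein BIM, fell 4.28-fold (95% confidence interval 3.64 to 5.03), and its 5 probe sets ranged from −2.10 to 0.12. Irs2, an adaptor of the insulin receptor, fell 3.79-fold (2.72 to 5.30), at a mean log2 intensity of 5.36 ± 0.47 against 7.29 ± 0.19 in Ctrl (SD, n = 3 per group). Plekhf1 fell 4.07-fold and the protease inhibitor gene Spint2 fell 4.01-fold (−0.98 on its other probe set, log2). The peptide transporter gene Slc15a2 was 3.76-fold lower on its brighter probe set (adjusted p = 0.0264; −0.50 on the other), and its call was lost without PTEN cKO replicate 2 (0.0909), PTEN cKO replicate 3 (0.0704) or Ctrl replicate 2 (0.0546).

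**Figure D1:**
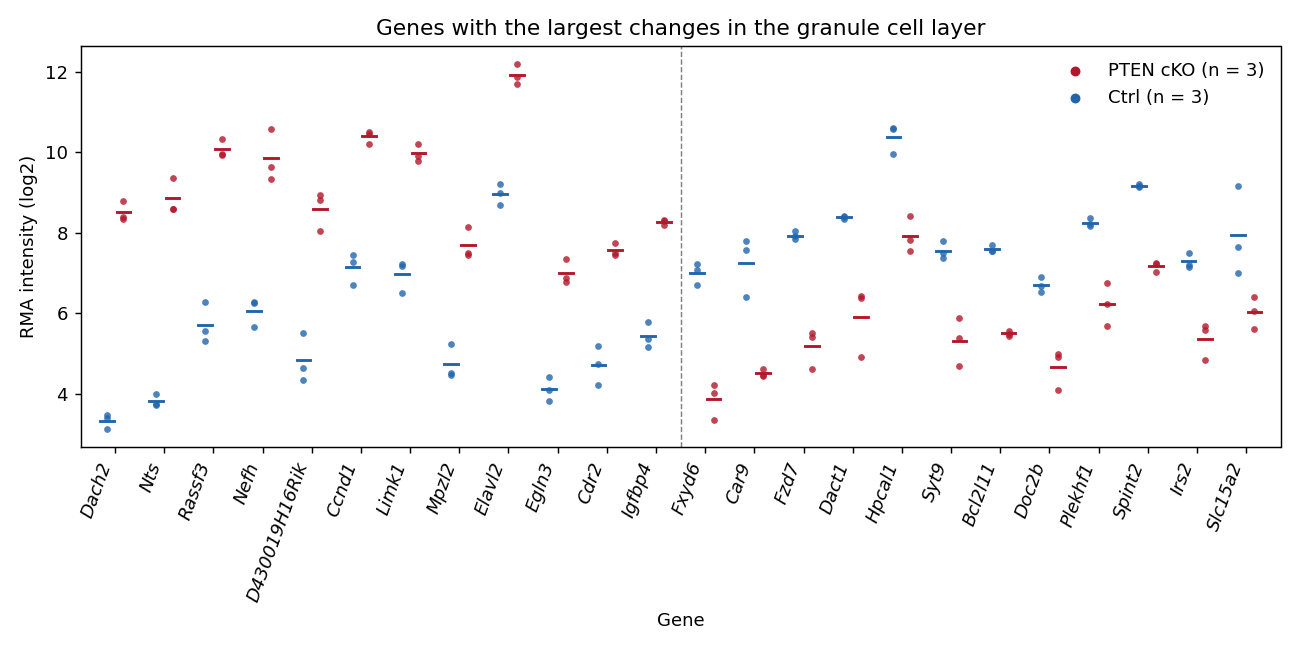
Log2 RMA intensity (vertical axis) of the 12 genes with the largest increases and the 12 with the largest decreases in PTEN cKO, left and right of the dashed line. Each point is 1 array (3 PTEN cKO, red; 3 Ctrl, blue), each short bar is a group mean, and the groups do not overlap for any gene shown, from Dach2 (means 8.51 and 3.33) to Slc15a2 (6.02 and 7.94).

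Genes of the PI3K pathway and of its transcriptional targets moved in both directions. Of 36 measured PI3K-AKT-mTOR pathway components, 3 rose and 4 fell (3 and 8 adjusted over the list alone). Pik3r1, the regulatory subunit p85-alpha, rose by 0.81 ± 0.11 (log2 fold change ± SE, as for the values that follow), while Irs2 (−1.92 ± 0.21), the ribosomal protein gene Rps6 (−1.14 ± 0.13) and the mTORC1 inhibitor gene Tsc1 (−0.57 ± 0.11) fell. The other probe set of Rps6 gave 0.09. Among 35 targets of FOXO transcription factors, which AKT holds out of the nucleus, 5 rose and 6 fell (5 and 10 adjusted over the list alone). Bcl2l11, Irs2 and, named after their values were seen, Foxo1 (−1.19 ± 0.26, with 4 probe sets from −1.19 to 0.11) and the cell cycle inhibitor gene Cdkn1b (−0.66 ± 0.13) fell, while Ccnd1, Ccnd2 and the stress-response gene Sesn3 (0.88 ± 0.10) rose. FOXO factors repress the D-type cyclins, so the counts mix induced and repressed targets. Without Ccnd1 and Ccnd2, 3 of 33 targets rose and 6 fell. In a test chosen after the result was seen, camera placed these 33 lower at the preset correlation (unadjusted p = 0.04312). With an estimated correlation, that camera p was 0.092. That correlation (0.0034) was below the preset one, so the higher p came with the lower degrees of freedom. The cell cycle list of 43 genes held 3 that rose and 3 that fell (the same numbers adjusted over the list alone). Its risers were the D-type cyclins Ccnd1 (3.26 ± 0.19) and Ccnd2 (2.16 ± 0.25, with 7 probe sets from −0.05 to 2.69) and the E-type cyclin Ccne1 (0.72 ± 0.18), whereas the replication helicase genes Mcm6 (−0.97 ± 0.13), Mcm7 (−0.75 ± 0.16) and Mcm4 (−0.56 ± 0.14) fell. Ccne1 and Mcm4 were named after their values were seen. The call of Ccne1 was lost without PTEN cKO replicate 1 (adjusted p = 0.0589), PTEN cKO replicate 2 (0.1), PTEN cKO replicate 3 (0.0583), Ctrl replicate 1 (0.0632) or Ctrl replicate 2 (0.0649), and that of Mcm4 without PTEN cKO replicate 1 (0.0811), PTEN cKO replicate 3 (0.1), Ctrl replicate 1 (0.0788), Ctrl replicate 2 (0.0794) or Ctrl replicate 3 (0.0713). The call of Mcm7 was lost without Ctrl replicate 2 (adjusted p = 0.0572) and with the mean of its probe sets (0.0812). Mcm6 lost its call after quantile normalization (−0.23, adjusted p = 0.404). That setting chose each gene's brightest probe set anew, so the loss may come from another probe set of Mcm6. In the list of p53 targets and cell death genes, 5 of 31 rose and 4 fell (5 and 5 adjusted over the list alone). There the pro-apoptotic gene Pmaip1 rose (2.18 ± 0.27) along with Zmat3 (1.10 ± 0.14), and Bcl2l11 and Sesn1 (−0.63 ± 0.11) fell. The set test camera, with a preset correlation between genes, called none of these 4 lists, with adjusted p = 0.199 for the pathway components, 0.373 for FOXO targets, 0.805 for the cell cycle and 0.577 for p53 targets. The rotation test fry called the PI3K-AKT-mTOR pathway components lower (adjusted p = 0.0447) and not the other 3. The cell cycle list had a positive mean (0.058) but a negative median (−0.053) and test direction.

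Neurofilament genes rose among the axonal genes. Of 44 axon growth and cytoskeleton genes, 8 rose and 4 fell (11 and 5 adjusted over the list alone). Nefh (3.79 ± 0.30), the light neurofilament gene Nefl (1.43 ± 0.15) and Stmn4, a stathmin that binds tubulin (1.76 ± 0.12), rose. Named after their values were seen, the medium chain gene Nefm (2.12 ± 0.43) and the internexin gene Ina (0.98 ± 0.12) also rose. The call of Nefm was lost without PTEN cKO replicate 2 (adjusted p = 0.053). The growth cone genes Basp1 (−1.30 ± 0.12) and, named after their values were seen, Marcks (−1.38 ± 0.15) and Dpysl3 (−1.40 ± 0.16, with 3 probe sets from −1.40 to 0.06) fell. Of 56 genes of axonal cell adhesion and axon-glia contact, 13 fell and 4 rose (20 and 6 adjusted over the list alone). Those that fell included the teneurin gene Tenm1 (−1.11 ± 0.13) and the immunoglobulin-family gene Alcam (−1.06 ± 0.13). Those that rose were the axonal surface glycoprotein gene Thy1 (2.07 ± 0.11), the Notch ligand gene Dll1 (1.91 ± 0.21) and, named after their values were seen, Cdh10 (1.03 ± 0.13) and Cntn4 (1.33 ± 0.18). Neither list passed the set test (adjusted p = 0.0605 for both), but both calls depended on the setting. With an intensity trend, robust or not, Axon growth and cytoskeleton genes were called higher (0.0421) and Axonal cell adhesion and axon-glia contact genes lower (0.0475). Axon growth and cytoskeleton genes were also called with the mean of all probe sets (0.0294), without the genes under the median intensity (0.0358), without PTEN cKO replicate 1 (0.00569) and without Ctrl replicate 2 (0.0264), and Axonal cell adhesion and axon-glia contact genes without PTEN cKO replicate 3 (0.0326). Markers of oligodendrocytes, the cells that ensheath axons, were also lower in PTEN cKO, by a median of −0.45.

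Secreted factors and matrix genes changed in both directions. In the list of 70 growth factors and secreted neuron-to-glia signals, 13 rose and 8 fell (14 and 9 adjusted over the list alone, set test adjusted p = 0.252). Besides Nts (5.04 ± 0.20), the increases included the neuregulin gene Nrg3 (1.51 ± 0.14), the activin subunit gene Inhba (2.14 ± 0.21) and the dense-core granule gene Chga (1.09 ± 0.12). Nrg3 had a second probe set at −0.03. Of 57 extracellular matrix genes, 8 rose and 1 fell (12 and 1 adjusted over the list alone). The metalloproteinase gene Mmp17 rose (1.35 ± 0.18), as did Sparcl1 (0.90 ± 0.12), the metalloproteinase inhibitor gene Timp3 (1.06 ± 0.14) and the aggrecanase gene Adamts5 (0.90 ± 0.13). The gene that fell was Hapln2 (−0.46 ± 0.12), named after its value was seen, and its call was lost in 5 of 6 fits that left out an array (adjusted p of 0.0671 to 0.141 there; without Ctrl replicate 1 it was kept). The set test placed the Extracellular matrix genes higher (adjusted p = 0.0305), a call lost with an estimated correlation (adjusted p = 0.301), without Ctrl replicate 3 (0.0613), without the genes under the lower quartile (0.0797), and with the mean (0.0599) or the most variable (0.0585) of a gene's probe sets. The estimated correlation (−0.00078) was below the preset 0.01, so the loss there came with the lower degrees of freedom. With those of the preset test, in a run added after the data were seen, camera gave adjusted p = 0.0075. Markers of blood vessel cells were also higher, by a median of 0.11.

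Granule cell markers were lower. The set test placed the granule list lower (adjusted p = 7.69e-05, but adjusted p = 0.303 with an estimated correlation). Of 28 such genes, 8 fell and 0 rose (11 and 0 adjusted over the list alone), with a median of −0.26. A run added after the data were seen used the estimated correlation (0.11) but the degrees of freedom of the preset test. There camera gave adjusted p = 0.0532 for the granule list. The guanine exchange factor gene Tiam1 (−1.60 ± 0.19) and the transcription factor genes Neurod2 (−0.89 ± 0.12), Zic2 (−0.72 ± 0.12) and Neurod1 (−0.60 ± 0.10) fell. A second probe set of Tiam1 gave −0.16. Gabra6, the GABA-A receptor subunit typical of granule cells and named after its value was seen, had a difference of −0.07 ± 0.10 at a mean log2 intensity of 13.3 in PTEN cKO and 13.4 in Ctrl (adjusted p = 0.727). Glutamate and GABA receptor genes held 4 that fell and 1 that rose of 35 (the same numbers adjusted over the list alone, set test adjusted p = 0.0605). Glutamate and GABA receptor genes were called lower with an intensity trend, robust or not (0.0421), under fry (0.0247) and without PTEN cKO replicate 3 (0.0454). The GABA-B receptor gene Gabbr1 (−0.90 ± 0.13, with probe sets from −0.90 to 0.04) and the NMDA receptor subunit gene Grin2c (−1.08 ± 0.22) fell, the former without its call when its 4 probe sets were averaged (adjusted p = 0.137). Markers of Purkinje cells, which lie beside the layer and receive granule cell input, were also lower in PTEN cKO, by a median of −0.78.

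Genes of transmitter release, excitability and activity responses changed without a common direction. Of 32 presynaptic vesicle genes, 4 rose and 7 fell (6 and 7 adjusted over the list alone, set test adjusted p = 0.394). The vesicle priming gene Cadps (1.00 ± 0.10) and the SNARE gene Vamp1 (1.56 ± 0.18) rose, and Doc2b (−2.03 ± 0.22) and Syt4 (−0.85 ± 0.12) fell. Potassium, sodium and calcium channel genes were split evenly, with 7 of 54 higher and 7 lower (9 and 10 adjusted over the list alone, adjusted p = 0.901). Kcnn2 (0.96 ± 0.12), a calcium-activated potassium channel, and the leak channel gene Kcnk2 (0.92 ± 0.13) rose, while the calcium channel subunit gene Cacna2d1 (−0.77 ± 0.12) and the BK channel subunit gene Kcnmb4 (−0.87 ± 0.14) fell. For these channels the median was −0.0049 and the mean 0.0094. Among 35 activity-regulated immediate early genes, 6 rose and 3 fell (8 and 6 adjusted over the list alone, adjusted p = 0.651). Dusp6, a phosphatase that acts on ERK (2.00 ± 0.18), Arc (1.57 ± 0.15) and Jun (1.31 ± 0.13) rose, while Egr1 fell (−1.69 ± 0.13). That list had a median of −0.052 and a mean of 0.019.

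Genes of cholesterol synthesis were higher. The set test placed the list of SREBP2 targets higher (adjusted p = 0.000665, but adjusted p = 0.294 with an estimated correlation). That correlation (−0.022) was below the preset 0.01, so the loss came with the lower degrees of freedom. With the degrees of freedom of the preset test, in a run added after the data were seen, camera gave adjusted p = 0.00061. Of 19 such targets, 6 rose and 0 fell (7 and 0 adjusted over the list alone), and 16 had a positive difference. The lanosterol demethylase gene Cyp51 (1.04 ± 0.11), the squalene epoxidase gene Sqle (0.74 ± 0.14) and Dhcr7, the enzyme of the last step to cholesterol (0.66 ± 0.11), rose. Fatty acid synthesis genes had no such direction, with 2 of 22 higher and 2 lower (the same numbers adjusted over the list alone, set test adjusted p = 0.651). The desaturase gene Scd1 fell (−0.80 ± 0.14) and the lipogenesis regulator gene Thrsp rose (0.67 ± 0.13). In the glycolysis and HIF1 target list, 1 of 28 rose and 5 fell (the same numbers adjusted over the list alone, adjusted p = 0.189). Egln3 (2.89 ± 0.19) was the gene that rose, and Car9 (−2.75 ± 0.31), Hif1a itself (−0.83 ± 0.10) and the lactate dehydrogenase gene Ldha (−0.71 ± 0.13) fell. The 4 probe sets of Hif1a ranged from −1.48 to 0.01.

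Amino acid response and endoplasmic reticulum genes were higher as sets at a preset correlation. The set test gave adjusted p = 0.0104 for the ATF4 list and 0.000812 for the ER list, but adjusted p = 0.331 and 0.467 with an estimated correlation. That correlation was 0.042 for the ATF4 list and 0.416 for the ER list, above the preset 0.01. With the degrees of freedom of the preset test, in a run added after the data were seen, camera gave adjusted p = 0.0957 and 0.355. Of 38 ATF4 and amino acid response genes, 6 rose and 2 fell (the same numbers adjusted over the list alone). The increases included the neutral amino acid transporter gene Slc1a4 (1.47 ± 0.15), the proline synthesis gene Aldh18a1 (1.14 ± 0.12), the glutathione-degrading enzyme gene Chac1 (1.09 ± 0.16) and the mitochondrial folate enzyme gene Mthfd2 (0.89 ± 0.15). The 2 that fell, Phgdh (−0.80 ± 0.22) and Psat1 (−0.40 ± 0.11), encode enzymes of serine synthesis. The 4 probe sets of Phgdh ranged from −0.80 to 0.0677, and its direction turned with the probe set of largest spread (0.0677). Both were named after their values were seen. Psat1 lost its call in each fit that left out an array (adjusted p of 0.0585 to 0.131), and Phgdh without Ctrl replicate 1 (0.13), Ctrl replicate 2 (0.129), PTEN cKO replicate 2 (0.106) or PTEN cKO replicate 3 (0.0601). Of 28 ER chaperone and unfolded protein response genes, 2 rose and 0 fell (2 and 0 adjusted over the list alone), and 21 had a positive difference. Eif2ak3, which encodes the ER stress kinase PERK, rose (1.11 ± 0.11), as did Atf6 (0.63 ± 0.14), whose call was lost without PTEN cKO replicate 1 (adjusted p = 0.0564), PTEN cKO replicate 2 (0.0689) or Ctrl replicate 2 (0.0594). The values of Manf (1.17 ± 0.34, adjusted p = 0.0533) and Dnajb11 (0.75 ± 0.22, adjusted p = 0.0563) did not pass as run. Some other settings called them, such as an intensity trend for Manf (limma adjusted p = 0.042) and a robust trend for both (0.0403 and 0.0485).

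Lists of protein synthesis, respiration and lysosome genes were not called by the set test as run, but 3 of the 4 were under other settings. Of 43 cytosolic ribosomal protein genes, 0 rose and 2 fell (0 and 2 adjusted over the list alone, set test adjusted p = 0.0595), Rps6 and Rps25 (−0.74 ± 0.17). Cytosolic ribosomal proteins were called lower after quantile normalization (0.0103), with an intensity trend, robust or not (0.0354), and without PTEN cKO replicate 1 (0.0384), PTEN cKO replicate 3 (0.0147), Ctrl replicate 1 (0.0161) or Ctrl replicate 3 (0.0109). The call of Rps25 was lost without PTEN cKO replicate 1 (adjusted p = 0.0668), PTEN cKO replicate 3 (0.0693), Ctrl replicate 2 (0.0575) or Ctrl replicate 3 (0.0534). In ribosome biogenesis, 0 of 37 genes rose and 4 fell (0 and 4 adjusted over the list alone, set test adjusted p = 0.252), namely Imp3, Polr1c, Imp4 and Utp18, with values from −0.52 to −0.40. Each of these 4 lost its call in at least 3 of the fits that left out an array, with adjusted p up to 0.082 for Imp3, 0.0916 for Polr1c, 0.12 for Imp4 and 0.123 for Utp18. Among 69 oxidative phosphorylation genes, Uqcrq rose (0.56 ± 0.16, with 4 probe sets from −0.06 to 0.56) and 0 fell (0 and 0 adjusted over the list alone, set test adjusted p = 0.129). Oxidative phosphorylation was called higher with the mean (0.0294) or the most variable (0.026) of a gene's probe sets and without Ctrl replicate 2 (0.0212). The call of Uqcrq was lost in all fits that left out an array except the one without Ctrl replicate 2 (adjusted p of 0.0778 to 0.131). Lysosome and autophagy genes held 5 that rose and 1 that fell of 40 (the same numbers adjusted over the list alone, set test adjusted p = 0.094), with Ctsz, a lysosomal protease gene, at 1.28 ± 0.28. Lysosome and autophagy was called higher with the mean (0.0402) or the most variable (0.0332) of a gene's probe sets and without Ctrl replicate 1 (0.0398). The call of Ctsz was lost without PTEN cKO replicate 2 (adjusted p = 0.0641), PTEN cKO replicate 3 (0.058) or Ctrl replicate 2 (0.0548).

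Markers of cell types other than granule cells also differed between the groups. Of 29 oligodendrocyte and myelin genes, 9 fell and 0 rose (14 and 0 adjusted over the list alone), with a median of −0.45. The myelin enzyme gene Cnp fell by 0.93 on the log2 scale (SE 0.14), as did Gpr37 (−0.73 ± 0.14) and Cldn11 (−0.84 ± 0.17), the last losing its call without PTEN cKO replicate 3 (adjusted p = 0.0505). Mbp, named after its value was seen, was lower by −0.45 ± 0.10 on its brightest probe set, and its call was lost without PTEN cKO replicate 1 (0.0594) or PTEN cKO replicate 2 (0.0545). Of 16 Purkinje cell markers, 6 fell and 0 rose (9 and 0 adjusted over the list alone), with a median of −0.78. Dner (−1.34 ± 0.16), Gng13 (−1.47 ± 0.24) and Pcp2 (−0.98 ± 0.21) fell, and Pcp2 lost its call without PTEN cKO replicate 2 (0.063). Calb1, named after its value was seen, had a difference of −1.70 ± 0.62 that did not pass (adjusted p = 0.112). Of 13 oligodendrocyte precursor markers, 2 fell and 0 rose (3 and 0 adjusted over the list alone), Rlbp1 (−1.35 ± 0.23) and Ednrb (−0.73 ± 0.17). Cspg5 (−0.73, limma adjusted p = 0.0568) and Nkx2-2 (−0.37, 0.13) did not pass, and 3 of the 13 had a positive difference. The 2 calls thus do not show a fall of the list as a whole. The call of Ednrb was lost without PTEN cKO replicate 2 (0.0873), PTEN cKO replicate 3 (0.0876) or Ctrl replicate 2 (0.0834). The set test placed oligodendrocyte and Purkinje markers lower (adjusted p = 1.5e-06 and 5.31e-05, but adjusted p = 0.294 and 0.303 with an estimated correlation), and the precursor markers did not pass (0.0783). A run added after the data were seen used the estimated correlation but the degrees of freedom of the preset test. There camera gave adjusted p = 0.0017 for oligodendrocyte and 0.0532 for Purkinje markers. Oligodendrocyte precursor markers were called lower under fry (0.0363) and without Ctrl replicate 1 (0.0398) or PTEN cKO replicate 3 (0.0454).

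Inhibitory neuron and astrocyte markers were lower as sets at a preset correlation, but not in every array or gene. The set test gave adjusted p = 0.0339 for the Inhibitory interneuron and unipolar brush cell markers and 0.0377 for the Astrocyte and Bergmann glia markers, but adjusted p = 0.35 and 0.303 with an estimated correlation. For the astrocyte list that correlation (−0.013) was below the preset 0.01, so its loss came with the lower degrees of freedom. With those of the preset test, in a run added after the data were seen, camera gave adjusted p = 0.0374 for it. The same run gave 0.185 for the interneuron list, whose estimated correlation was 0.089. Among 15 inhibitory interneuron and unipolar brush cell markers, 6 fell and 1 rose (the same numbers adjusted over the list alone). Gad1 (−1.24 ± 0.12), Gad2 (−0.97 ± 0.14) and the vesicular GABA transporter gene Slc32a1 (−1.48 ± 0.14), which Purkinje cells also express, fell, and Elavl2 (2.95 ± 0.17) rose. Of 27 astrocyte and Bergmann glia markers, 6 fell and 2 rose (7 and 3 adjusted over the list alone). Gfap (−0.73 ± 0.12) and Ntsr2, a neurotensin receptor gene (−0.89 ± 0.18), fell, whereas Fabp7 (2.31 ± 0.16) and Id4 (0.80 ± 0.15) rose. Of 30 reactive astrocyte genes, 4 rose and 1 fell (4 and 2 adjusted over the list alone, set test adjusted p = 0.438), with Serpina3n at 1.45 ± 0.21. The call of the Inhibitory interneuron and unipolar brush cell markers was lost without PTEN cKO replicate 2 (adjusted p = 0.0598) or Ctrl replicate 3 (0.109), and that of the Astrocyte and Bergmann glia markers without Ctrl replicate 2 (0.0644) or Ctrl replicate 3 (0.0613). Both were lost without the genes under the median intensity (0.182 and 0.225) and with array weights (0.0624 and 0.0522), and that of the Astrocyte and Bergmann glia markers also without the genes under the lower quartile (0.0633). Among astrocyte markers with a mean log2 of at least 6, PTEN cKO replicate 2 stood apart, with a mean deviation of −0.235 from the average of all arrays. PTEN cKO replicates 1 and 3 (0.015 and 0.056) overlapped with or lay close to Ctrl (0.024 to 0.074) there. Without PTEN cKO replicate 2 the median of the Astrocyte and Bergmann glia markers was −0.20 instead of −0.28, and the call was kept (adjusted p = 0.0359). For interneuron markers of that brightness the groups overlapped too, at −0.234 to 0.071 in PTEN cKO and 0.0024 to 0.201 in Ctrl.

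Vascular markers were higher and immune markers showed few changes. The set test placed the Endothelial, pericyte and smooth muscle markers higher (adjusted p = 0.0339, but adjusted p = 0.35 with an estimated correlation), a call lost without PTEN cKO replicate 3 (0.0834) or Ctrl replicate 3 (0.172), without the genes under the lower quartile (0.0535) or the median intensity (0.186), and with array weights (0.0522). With the estimated correlation (0.068) but the preset test's degrees of freedom, a run added after the data were seen, camera gave adjusted p = 0.185. Of 29 endothelial, pericyte and smooth muscle markers, 4 rose and 1 fell (the same numbers adjusted over the list alone). The tight junction gene Cldn5 (0.91 ± 0.13), the transcription factor gene Ets1 (2.28 ± 0.38) and Itm2a (0.67 ± 0.13) rose. The 4 probe sets of Ets1 ranged from −0.09 to 2.28. Of 30 microglia and macrophage markers, 2 rose and 0 fell (1 and 0 adjusted over the list alone, set test adjusted p = 0.56), among them Lyz2 (0.74 ± 0.14), and the list had a median of −0.013 and a mean of 0.042. The interferon and antigen presentation list of 35 genes held Stat2, which fell (−1.08 ± 0.15, with a second probe set at 0.02), and the class II gene H2-Aa, which rose (1.21 ± 0.25), the same numbers adjusted over the list alone (set test adjusted p = 0.0798). Of 6 erythrocyte genes, Slc4a1 rose (0.91 ± 0.25) and 0 fell (1 and 0 adjusted over the list alone, set test adjusted p = 0.275), a call lost in 5 of 6 fits that left out an array (adjusted p of 0.0866 to 0.123; without PTEN cKO replicate 2 it was kept). None of 16 markers of meninges, fibroblasts and choroid plexus passed, with 0 adjusted over the list alone (set test adjusted p = 0.901), and the decorin gene Dcn was at −0.62 ± 0.22 (adjusted p = 0.0985). That list had a median of 0.0004 and a mean of −0.047.

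**Figure D2:**
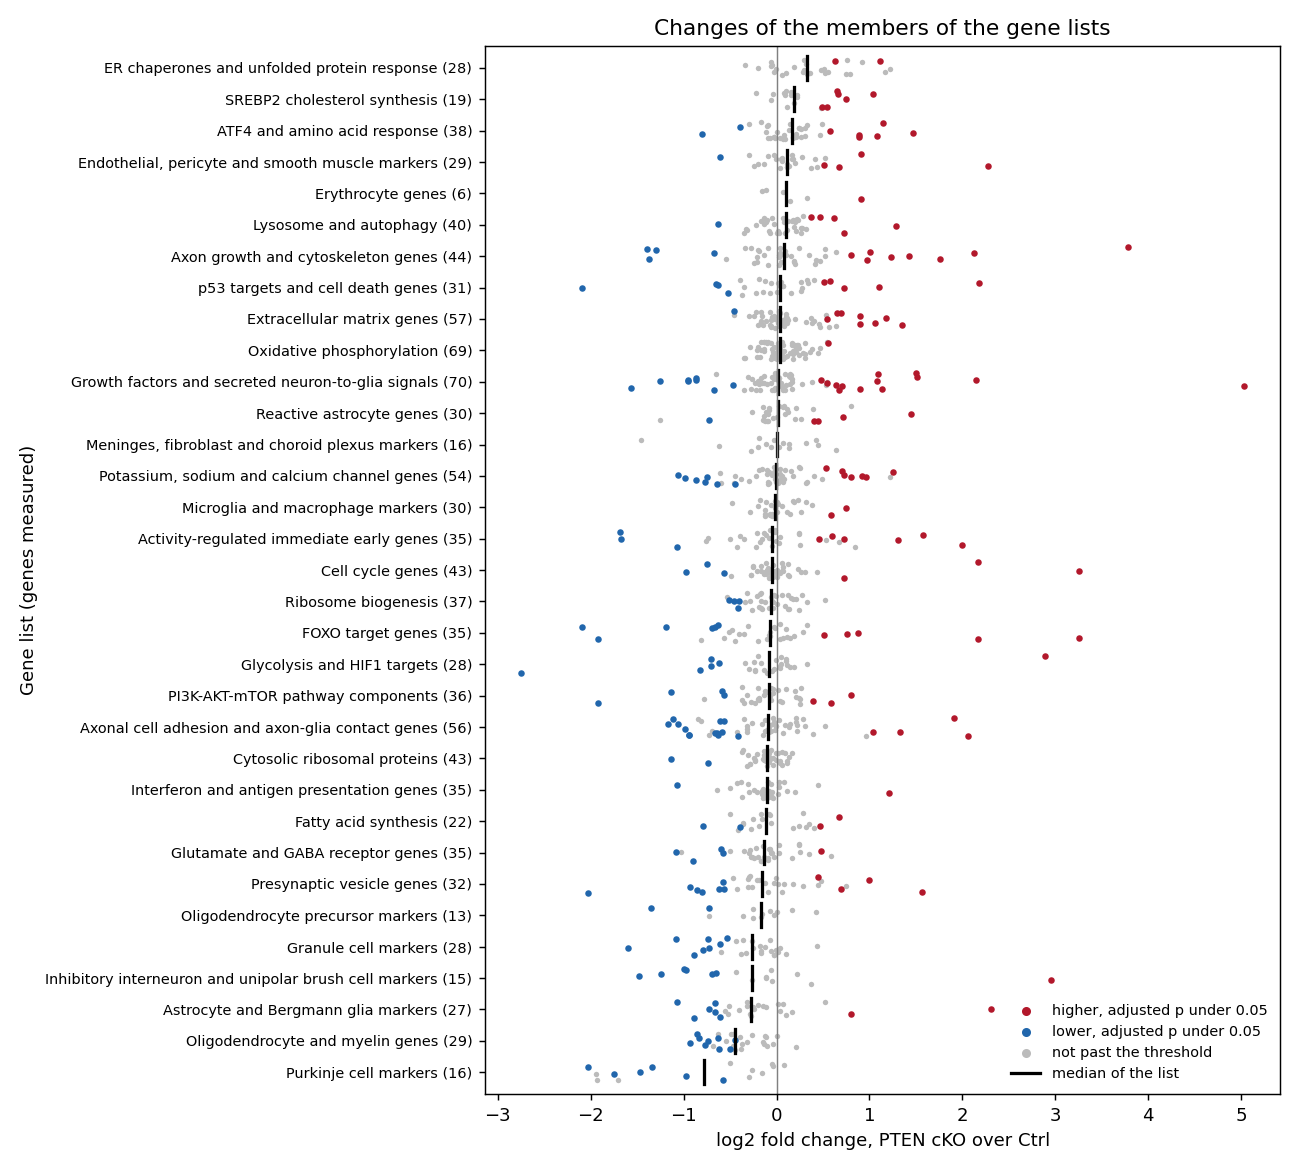
Log2 fold change of PTEN cKO over Ctrl (horizontal axis) for the measured members of 33 gene lists, whose sizes stand in parentheses. Each point is 1 gene, red or blue where higher or lower at an adjusted p under 0.05 and grey otherwise, and each black bar is a list's median, from −0.78 for Purkinje cell markers to 0.33 for ER chaperones and unfolded protein response.

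The set test called 10 of the 33 lists, 5 higher and 5 lower, when the correlation between genes was preset at 0.01, and none of these calls held with an estimated correlation, with which 4 lists had an unadjusted camera p under 0.05. That test also takes its degrees of freedom from the 6 arrays (4), and with the estimated correlation but the larger degrees of freedom, a run added after the data were seen, 4 calls held, those of the SREBP2, extracellular matrix, oligodendrocyte and astrocyte lists. The ER and endothelial calls were also lost under the rotation test fry (adjusted p = 0.17 and 0.109), which asks whether a set's genes move one way on balance and compares them with no other genes. Fry called 5 further lists, PI3K-AKT-mTOR pathway components and Glycolysis and HIF1 targets lower (0.0447 for both), Glutamate and GABA receptor genes and Oligodendrocyte precursor markers lower (0.0247 and 0.0363), and Growth factors and secreted neuron-to-glia signals higher (0.0247).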

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

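The tests of RNA integrity and of other splits of the arrays were set before their results were seen, and the tests on cell type markers and on cyclins were chosen after the result was seen. Probe sets left out of the gene tests also differed between the groups. Of 1555 probe sets with no gene named, 107 (6.88%) passed the threshold, 48 higher and 59 lower in PTEN cKO. Of 691 probe sets that name several genes, 47 (6.80%) passed, 31 higher and 16 lower, against 2042 of the 20380 probe sets with 1 gene.

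The overall difference between the groups covered 1548 genes. The highest count for any other split of the 6 arrays into 3 and 3 was 0, so 1 of the 10 splits, the real one, gave as many, and 10 splits are too few for a share under 0.05. For gene lists the real split gave 10 and the highest other 7, again 1 of 10 splits. Each other split puts arrays of both groups on each side. The group difference then stays in part in the contrast and widens the spread within sides. The counts of the other splits are thus no clean reference for chance. In PTEN cKO and Ctrl, the 3' signal exceeded the 5' signal by means of 6.41 and 6.09 (log2) for Gapdh. The excess was 5.59 and 5.70 for actin, and 0.29 and 0.39 for the transferrin receptor. Probe sets far from a 3' end may thus be dim in both groups. For RNA integrity or amplification length, the 3' minus the 5' signal differed by 0.3175 (log2, PTEN cKO minus Ctrl) for Gapdh and by −0.11 for actin. SDs in PTEN cKO and Ctrl were 0.35 and 0.26 for Gapdh, and 0.16 and 0.18 for actin. The test asked for groups fully apart in the same direction for both Gapdh and actin. That was not met, as the groups overlapped for both. With 3 arrays per group a modest difference could fail this test, so such a difference stays open. An effect of the genotype stays open as a hypothesis.

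Markers of Purkinje cells and of oligodendrocytes were lower in PTEN cKO captures. A smaller share of every other cell type would lower vascular markers too, but these were not lower. Among markers with a mean log2 of at least 6, the median difference of 10 vascular markers (0.22) lay 0.6942 above that of 20 oligodendrocyte markers (−0.47; permutation p = 0.0005 over genes, which are not independent replicates). The 2 lists had already been called in opposite directions when this test was chosen, so its p is no independent support. Ctrl replicate 3 weighed on the vascular side, with a mean deviation of −0.288 from the average of all arrays. The other Ctrl replicates had 0.036 and −0.100, and PTEN cKO 0.084 to 0.183. For Purkinje markers of that brightness, PTEN cKO replicate 1 stood apart, with a mean deviation of −1.29 from the average of all arrays. PTEN cKO replicates 2 and 3 had −0.28 and −0.40, and Ctrl 0.33 to 0.94. Less Purkinje cell material stays a possible account of the Purkinje part. Of such markers, 7 of 7 were lower with a median of −1.47, which lower expression per cell would give as well. Their deviations within groups correlated at a mean of 0.215, at percentile 90.76 of random lists matched on mean expression, which falls short of the 95 set for the test, so that less material and lower expression per cell cannot be told apart. Fewer oligodendrocytes near the captured cells or lower myelin gene expression in PTEN cKO stay open and were not tested.

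The D-type cyclin genes Ccnd1 and Ccnd2 rose, in a layer made mostly of non-dividing neurons. The other D-type cyclin gene, Ccnd3, had a difference of 0.23 that did not pass (limma adjusted p = 0.377 with all probe sets tested together). A single cross-hybridising probe set is argued against, as 8 probe sets passed, 3 of 3 for Ccnd1 and 5 of 7 for Ccnd2. More dividing cells would raise other cell cycle genes too. With Ccnd3 also set aside, the 9 others with a mean log2 of at least 6 had a median difference of −0.1157 (95% bootstrap interval −0.56 to 0.31). The 40 others of any brightness had −0.063 (−0.12 to −0.0026). These intervals resample genes, which are not independent replicates, and leave out the spread between arrays. Both medians lie far below the change of Ccnd1 and Ccnd2. The dimmer gene Ccne1 rose by 0.72, the most of the 40. The other genes thus showed no common rise of the cyclins' size. Only 9 of the 40 were that bright, so a small rise in dividing cells is not excluded. Less transcription by FOXO factors, which repress D-type cyclins, remains a hypothesis. The 33 other FOXO targets were lower as a set at a preset correlation (unadjusted camera p = 0.04312), but 3 of them rose while 6 fell. With an estimated correlation the camera p was 0.092. That correlation (0.0034) was below the preset one, so the higher p came with the lower degrees of freedom and not with the correlation.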

How the results depend on the processing

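All alternatives but 1 were planned before the data were examined. Other choices of moderation, scaling, filter, probe set summary or array weights gave 767 to 875 genes higher (832 as reported) and 667 to 814 lower (716 as reported), all within 1.5 times, as did testing all probe sets together. Leaving out 1 array gave 508 to 723 higher and 422 to 729 lower genes, the lowest counts without PTEN cKO replicate 2, in tests with fewer samples. Of the 1548 genes called, 886 to 1205 were called in the same direction without 1 array and 1242 to 1529 under those other choices. The lists called were less stable. Of 5 higher and 5 lower lists, the count of lower lists became 8 with an intensity trend, 8 with a robust trend, 9 under fry, 3 without the genes under the median intensity and 3 with array weights. The count of higher lists became 3 without the genes under the lower quartile, and both counts became 0 with an estimated correlation. With that correlation but the degrees of freedom of the preset test, an alternative chosen after seeing the data, 2 lists were higher and 2 lower. Leaving out 1 array gave 3 to 7 higher and 4 to 9 lower lists, with 3 higher without Ctrl replicate 3 and 9 lower without PTEN cKO replicate 3. The cause was not tested. With the replicate number as a replicate block, 665 genes were higher and 597 lower, and 5 lists were higher and 5 lower. Deviations of same-numbered arrays correlated at 0.002, −0.121 and −0.0876, so the numbers were not taken to pair samples. Over 170 named genes, 2422 of 2680 values stayed on their side of the threshold, 216 lost and 41 gained a call, and 104 of 148 called genes kept theirs throughout. The 1 reversal was Phgdh, at 0.0677 with its probe set of largest spread, another probe set by construction. Alternatives for Pten gave no value. Dim signals limit the sizes of folds from genes near the lower quartile.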

Other observations

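All tests in this part were chosen after the data were examined. A screen covered 210 gene families, formed from symbols that share a stem and have at least 8 measured members. It called 2 by camera at the preset correlation, no more than the up to 2 that other splits of the arrays gave, and 0 with an estimated correlation. Those splits mixed both groups, so they are no clean reference for chance. Of 32 genes with the stem Ube, which holds ubiquitin-conjugating enzymes and some ubiquitin ligases, 12 rose and 0 fell in PTEN cKO. Ube2v2 rose by 1.06 ± 0.13 (log2 fold change ± SE) and Ube2g2 by 0.64 ± 0.12. Of 13 genes with the stem Kdm, which holds lysine demethylases, 5 fell and 0 rose, among them Kdm2b (−1.37 ± 0.18) and Kdm6a (−0.78 ± 0.13). These were the 2 families called (adjusted p = 0.0133 for Ube and 0.0369 for Kdm, but adjusted p = 0.977 for both with an estimated correlation).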
